A study of Mus musculus with 8 samples.

How the data were processed

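Gene expression was measured by RNA sequencing of whole mouse liver in 8 libraries of 3 groups. Per the labels' protocols, messenger RNA was isolated with oligo(dT) magnetic beads, fragmented with an RNase, ligated to adaptors, reverse transcribed and amplified with an Ion Torrent kit, and the libraries were read on an Ion Proton. Amplified reads without molecular identifiers are not independent molecules, so the intervals and detection floors given here cover counting error only. The labels name the samples of a group only by a replicate number and do not say that they come from separate animals, so the p-values measure the spread between these samples, which may be technical.

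The deposited values are raw read counts per Ensembl gene in a table of all 8 libraries, with the gene name, chromosome, start, end and strand of each gene, and the files of the single samples hold the same counts. Per the submitters' processing notes, TopHat2 2.0.9, Cufflinks and DESeq were used with the mm9 build of the mouse genome. The versions of Cufflinks and DESeq, the counting tool, the gene annotation, the strand setting and the handling of reads with several hits are not given in the sources used here. Values of genes that overlap another gene or have a near-identical copy are therefore uncertain, which is said where they are given or here: Abcc4, Acacb, Cacna1b, Ccl2, Ccna2, Col1a1, Dnaic1, Hist1h2bm, Nr1i3, Suv420h1, Tnfrsf12a and Vil1 overlap a gene on the opposite strand. The authors' table holds no fold changes or p-values, so no comparison of theirs was set beside the values here. Gene coordinates are those of the deposited table. A GENCODE M21 annotation and its transcripts, which belong to another build, were used for gene type, transcript GC content and the search for copies with blastn 2.17.0, and none of its coordinates were used. Ensembl identifiers matched that annotation for 96.6% of the genes.

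The table lists 37583 genes, of which 17362 passed the count filter of edgeR 4.0.16 (filterByExpr by group). Library sizes were scaled with TMM, and all 8 libraries entered 1 fit with the group as the only term, because 2 of the groups hold only 2 libraries and share the estimate of the spread with the others. The common biological coefficient of variation was 0.479. Differences were tested with edgeR's robust quasi-likelihood test and Benjamini-Hochberg adjustment over all tested genes, and a gene is said to have risen, fallen or changed at an adjusted p under 0.05. CPM values are counts scaled to the TMM-adjusted library size, given as mean ± SD over the libraries of a group. A fold against a group with 0 counts in all libraries is a lower bound computed against 3 counts over that group. For a group with 1 to 3 counts the ratio is given with a 95% counting interval. Total counts ran from 7305595 to 16108081 per library, at which 3 counts correspond to 0.411 and 0.186 CPM before scaling.

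The design, the named genes and the 39 gene lists were fixed before the data were examined. Named genes are Setd8 (the symbol of Pr-Set7), the 10 genes with the highest and the 10 with the lowest log2 fold change among those that changed, had a mean log2 CPM of 1 or more and no overlap between the groups, and up to 4 members of each list with the smallest adjusted p. For the contrast of PR-SET7_LOBE with DEN_WT the rule takes 6 and 6. Predicted or unnamed genes and immunoglobulin or T cell receptor segments were left out, and some genes of known interest in liver may be named with their values where they did not pass. Lists were tested with limma 3.58.1 (camera on log2 CPM with a prior count of 2 and a preset correlation of 0.01), adjusted over the 38 lists with at least 5 measured members. Camera asks whether a list moved more than the other genes. It was also run with an estimated correlation, and fry was run as a test of the list alone. Similarity of libraries was read from Pearson correlations and principal components of log2 CPM. No libraries of a group agreed within sampling noise: the lowest chi-square per degree of freedom between replicates was 30.3.

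The effects of both groups against WT use the same 2 WT libraries. Their agreement was therefore set beside 20 simulations of unchanged groups against those libraries. Alternatives fixed in advance were DESeq2 size factors (the RLE method), upper-quartile scaling, DESeq2 1.42.0, limma voom with quality weights, no filter and a strict filter (5 CPM in 2 libraries), fits on only the 2 groups compared, the replicate number as a block, leaving out each library in turn, and leaving out the 20 most abundant genes. A correction for GC content and a fit without pseudogenes were chosen after seeing the data. When a library of WT or DEN_WT was left out, the lone library was assumed to vary like those of the other groups.

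The steps were tested on simulated counts with 200 changed genes per comparison. For PR-SET7_LOBE against WT (16107 genes), 27 of 100 genes changed 4-fold and 79 of 100 changed 16-fold were recovered, with 4 false calls by edgeR, 2 by voom and 30 by DESeq2. For DEN_WT against WT (16105 genes) the recovered genes were 11 of 100 and 77 of 100, with 3, 2 and 38 false calls. For PR-SET7_LOBE against DEN_WT (16118 genes) they were 24 of 100 and 74 of 100, with 8, 3 and 49 false calls. The GC correction, tested for PR-SET7_LOBE against WT on 12454 genes, took a simulated GC correlation from 0.451 to 0.00739. Versions were R 4.3.3, Python 3.11.15 and matplotlib 3.10.9.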

Results

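Liver RNA of 8-month-old C57BL6/CBA mice was sequenced in 8 libraries. The WT group held 2 libraries of untreated wild-type livers, with 13757466 and 16108081 counts. The PR-SET7_LOBE group held 4 libraries of livers with Pr-Set7 inactivated in hepatocytes, with 12170293, 10086157, 7305595 and 8904838 counts; what LOBE stands for is not given in the labels. Pr-Set7 monomethylates histone H4. The DEN_WT group held 2 libraries of wild-type mice injected at 15 days of age with diethylnitrosamine (DEN), a liver carcinogen, with 10120058 and 10802335 counts. Its dose is labelled as 25 ml per kg, with no concentration.

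The DEN_WT libraries stood apart from the other 6. The first principal component held 42.8% of the variance and separated DEN_WT, and the second held 26.8%. Replicates correlated at r = 0.949 across genes in WT, 0.979 in DEN_WT and between 0.872 and 0.947 in PR-SET7_LOBE. PR-SET7_LOBE replicate 1 lay closer to WT (mean r = 0.923) than to the other PR-SET7_LOBE libraries (mean r = 0.890). Genes with at least 1 count numbered 18037 and 20781 in WT, 18681, 22249, 26437 and 24812 in PR-SET7_LOBE and 22271 and 21754 in DEN_WT. Pseudogenes held 2.23% and 2.60% of the counts in DEN_WT and between 1.05% and 1.57% in the other libraries. Deviations of gene levels followed GC content most in PR-SET7_LOBE replicate 1 (r = 0.682 across genes). With transcript length they correlated at 0.00951 and -0.208 in WT, -0.0904, -0.0685, 0.294 and 0.257 in PR-SET7_LOBE, and -0.0335 and -0.0368 in DEN_WT. The TMM factors were 0.760 and 0.674 in WT, 0.876, 1.038, 1.48 and 1.238 in PR-SET7_LOBE, and 1.117 and 1.049 in DEN_WT.

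**Figure D1:**
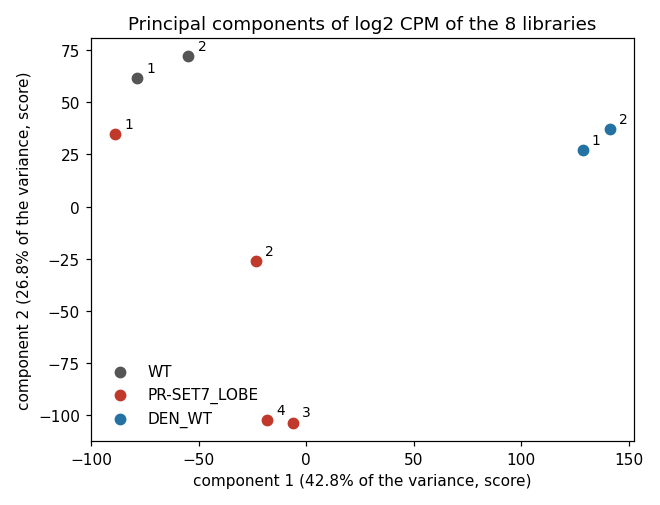
Scores of the 8 libraries on the first (x axis, 42.8% of the variance) and second (y axis, 26.8%) principal component of log2 CPM, 1 point per library with its replicate number. The 2 DEN_WT libraries lie apart on the first component, and PR-SET7_LOBE replicate 1 lies near the 2 WT libraries.

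Setd8, the gene of Pr-Set7 (ENSMUSG00000049327, mm9 chromosome 5, 124889939 to 124912317), had 51.9 and 56.0 CPM in the WT libraries, 62.6, 57.4, 47.9 and 46.5 CPM in the libraries labelled PR-SET7_LOBE, and 40.0 and 42.8 CPM in DEN_WT. The log2 fold change between the libraries labelled PR-SET7_LOBE and WT was -0.01 (SE 0.32, adjusted p = 0.994). In DEN_WT it was -0.38 against WT (SE 0.37, adjusted p = 0.517). The deleted exons are not given, the values are counts of the whole gene, and liver cells other than hepatocytes keep the gene, so Setd8 cannot check the genotype labels here. Directions below are those of the libraries labelled PR-SET7_LOBE. Suv420h1 and Suv420h2, which add further methyl groups to histone H4, had 25.2 ± 2.71 and 29.4 ± 11.2 CPM (SD, n = 4) against 26.4 ± 1.43 and 32.2 ± 6.63 CPM in WT (SD, n = 2), with adjusted p = 0.930 and 0.880.

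The first comparison asked what hepatocyte inactivation of Pr-Set7 changes in the adult liver. The detoxification enzymes Cbr3 and Gpx2, the cell cycle inhibitor Cdkn1a and the matrix protein Spp1, which cholangiocytes secrete, rose in the libraries labelled PR-SET7_LOBE, and Cyp46a1, a cholesterol hydroxylase, nearly disappeared. Cbr3, a carbonyl reductase (chromosome 16, 93683460 to 93691235), was at 51.5 ± 22.6 CPM (SD, n = 4) against 0.142 ± 0.0702 CPM in WT (SD, n = 2), a ratio of 364 with a 95% counting interval of 124 to 1770 (adjusted p = 0.00607). Cdkn1a (chromosome 17, 29227924 to 29237667) was at 49.8 ± 26.2 against 1.77 ± 0.883 CPM, a log2 fold change of 4.80 (SE 0.69, adjusted p = 0.0248). Cyp46a1 (chromosome 12, 109572587 to 109600441) was at 2.96 ± 2.82 against 318 ± 80.3 CPM, a log2 fold change of -6.74 (SE 0.73, adjusted p = 0.00607). Of 17362 genes, 26 rose and 17 fell. The groups did not overlap in any of these 43 genes. This follows largely from calling them on the same libraries and is no separate support, and the 13.3% that chance gives holds for unselected genes. Gpx2, a glutathione peroxidase, had no counts in WT and 82.8 ± 48.7 CPM in PR-SET7_LOBE, at least 588-fold higher (adjusted p = 0.0298). Ubd, an inflammation-induced ubiquitin-like modifier, reached 197 ± 177 against 0.471 ± 0.145 CPM, a log2 fold change of 8.68 (SE 1.35, adjusted p = 0.0331). Lrtm2 rose by 4.46 on the log2 scale (SE 0.73, adjusted p = 0.0373). Ppfia4, Phlda2 and Gldn had 3 counts each in WT. Their ratios were 61.8 (21 to 301), 59.6 (20.2 to 291) and 47.0 (15.9 to 229), with adjusted p = 0.0114, 0.0351 and 0.0331. The other named genes that fell were H2-Ea-ps, an MHC class II pseudogene (0.115 ± 0.137 against 24.4 ± 18 CPM, adjusted p = 0.00607), Dpy19l3 (log2 fold change -3.21, adjusted p = 0.0331) and Ugt1a5, a glucuronosyltransferase (17.7 ± 5.08 against 80.8 ± 14.7 CPM, adjusted p = 0.0331). Ugt1a5 overlaps 10 other genes on its strand, and Gpx2, Gldn and Lrtm2 overlap a gene on the opposite strand, so these values are uncertain. The mice were C57BL6/CBA, and which strain's copy of H2-Ea-ps each library carried was not measured. A strain difference at this gene is therefore not separated from the group. The same holds for the other genes that changed, such as Cyp46a1, Ubd, Dpy19l3 and Ugt1a5, whose strain copies were not measured either. The count of 43 genes was 8 without WT replicate 1, 1 without WT replicate 2, 15, 28 and 99 without PR-SET7_LOBE replicates 2, 3 and 4, and 2392 without PR-SET7_LOBE replicate 1, which shared all 43 genes; of 19 named genes that changed, 2, 1, 6, 14, 19 and 19 passed in these fits, with highest adjusted p = 0.222, 0.447, 0.1 and 0.0877 in the first 4. H2-Ea-ps and Cyp46a1 were those that passed without WT replicate 1, and H2-Ea-ps alone without WT replicate 2, so neither Cbr3 (0.0524 and 0.122 without WT replicates 1 and 2) nor Cdkn1a (0.170 and 0.237) passed with a single WT library. Without PR-SET7_LOBE replicate 2, 13 named genes were lost, among them Cdkn1a (0.0578), Spp1 (0.0831), Lrtm2 (0.0782), Gsta1 (0.0538), Dpy19l3 (0.0640) and Fabp4 (0.1), with 0.0648 each for Gpx2, Ubd, Phlda2, Gldn, Ugt1a5 and Igdcc4. Without replicate 3, Gsta1 (0.0570), Ugt1a5 (0.0877), Spp1, Dpy19l3 and Fabp4 (0.0623 each) were lost. A fit on only these 2 groups kept 9 of the 19 (highest adjusted p = 0.0669) and lost Spp1, Igdcc4, Fabp4, Gsta1, Gldn, Phlda2, Lrtm2, Dpy19l3 and Ugt1a5 among others. Voom lost Gpx2, Phlda2 and Gldn (highest adjusted p = 0.0683), and the fit without a count filter lost Ubd (0.0588). Without DEN_WT replicates 1 or 2 only Ugt1a5 was lost (adjusted p = 0.0577 and 0.0578). Upper-quartile scaling gave 47 higher and 19 lower genes, 71.2% higher in place of 60.5%, and moved the median of all genes from 0.11 to 0.29 on the log2 scale.

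Among the lists fixed in advance, 15 moved up and 15 moved down in PR-SET7_LOBE against WT with the preset correlation. None was called with an estimated correlation, where the lowest adjusted p was 0.0732, and fry called 10. The estimated correlation itself was below the preset 0.01 for the ductal (-0.00232), p53 (-0.0148) and T and NK cell lists (-0.0262). A higher correlation between members is therefore not what raised the adjusted p of these lists. For a simulated list of genes raised 4-fold, the adjusted p was 1.95e-39 with the preset and 0.000845 with the estimated correlation. The NRF2 and glutathione list, enzymes of the response to oxidants and electrophiles, moved up (adjusted p = 4.12e-09). Of its 21 measured members 3 rose and 18 did not pass over all genes, and 13 were higher adjusted over the list alone; adjusted p = 0.184 with an estimated correlation. Abcc4, an efflux transporter, was at 40.7 ± 14.0 against 3.10 ± 0.215 CPM (log2 fold change 3.71, SE 0.48, adjusted p = 0.0137). Gsta1 was at 165 ± 108 against 7.52 ± 2.92 CPM (adjusted p = 0.0331) but is uncertain, since it is 99.5% identical to Gm3776. Nqo1 was at 40.2 ± 25.4 against 3.40 ± 1.42 CPM and did not pass (adjusted p = 0.0729). The oncofetal and hepatocellular carcinoma list moved up (adjusted p = 3.69e-10, and adjusted p = 0.0732 with an estimated correlation), with 2 of 23 members higher over all genes, and 17 higher and 1 lower adjusted over the list alone. The members that passed were Igdcc4 and Cbr3, which is also on the NRF2 list. Igdcc4 was at 23.0 ± 14.0 against 1.17 ± 0.0355 CPM (adjusted p = 0.0331), whereas Gpc3 (11 ± 5.13 against 1.82 ± 0.948 CPM, adjusted p = 0.0854) and Afp (13.1 ± 12.8 against 2.49 ± 0.000739 CPM, adjusted p = 0.181) did not pass. H19 and Igf2, also on this list, were high in only some PR-SET7_LOBE libraries, with values given under the other observations. The ductal and progenitor list moved up (adjusted p = 1.19e-06, and adjusted p = 0.0732 with an estimated correlation), with 1 of 24 members higher over all genes, and 12 higher and 1 lower adjusted over the list alone. That member was Spp1, at 171 ± 75.2 against 12.3 ± 4.57 CPM (adjusted p = 0.0411). Sox9 was at 29.6 ± 13.9 against 5.53 ± 2.87 CPM (adjusted p = 0.0954), Epcam at 2.98 ± 1.81 against 1.04 ± 0.692 CPM (adjusted p = 0.330), Cd24a at 4.51 ± 2.98 against 0.932 ± 0.507 CPM (adjusted p = 0.185) and Krt19 at 2.45 ± 1.86 against 2.54 ± 0.731 CPM (adjusted p = 0.977). The G2 and mitosis list moved up (adjusted p = 2.1e-11, and adjusted p = 0.140 with an estimated correlation), with 0 of 26 members passing over all genes, and 16 higher and 1 lower adjusted over the list alone. Mki67 was at 11.3 ± 9.07 against 0.993 ± 0.491 CPM (adjusted p = 0.117). The p53 target list moved up (adjusted p = 0.00534, and adjusted p = 0.140 with an estimated correlation), with Cdkn1a and Phlda3 (39.3 ± 11.9 against 2.63 ± 0.196 CPM, adjusted p = 0.0109) higher among 25 members, and 5 higher and 1 lower adjusted over the list alone. Chemokines moved up (adjusted p = 3.08e-06, and adjusted p = 0.214 with an estimated correlation), with 0 of 20 members passing over all genes and 7 higher adjusted over the list alone; Ccl2 was at 9.23 ± 4.88 against 0.713 ± 0.617 CPM (adjusted p = 0.0975). S phase genes moved up (adjusted p = 0.00128, and adjusted p = 0.281 with an estimated correlation), with 0 of 25 members passing over all genes, and 6 higher and 1 lower adjusted over the list alone. The estimated correlation gave the highest adjusted p of the 14 alternatives for each of these 7 lists, and the lowest were, in the order named, 5.37e-12, 1.89e-14, 1.13e-07, 1.32e-12, 0.000716, 6.09e-09 and 4.75e-05. Fry lost chemokines (adjusted p = 0.0588) and S phase (0.0633). All 7 lists passed with any library left out.

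Lists of hepatocyte function moved down. Urea cycle and amino acid catabolism moved down with adjusted p = 2.98e-09 (adjusted p = 0.184 with an estimated correlation), with 0 of 22 members passing over all genes and 11 lower adjusted over the list alone. Agxt, which detoxifies glyoxylate, was at 122 ± 78.0 against 489 ± 35.1 CPM (adjusted p = 0.134). Cytochrome P450 genes moved down with adjusted p = 1.35e-05 (adjusted p = 0.175 with an estimated correlation), with 0 of 21 members passing over all genes, and 2 higher and 7 lower adjusted over the list alone. Gluconeogenesis and glycogen moved down with adjusted p = 1e-05 (adjusted p = 0.140 with an estimated correlation), with 0 of 14 members passing over all genes and 2 lower adjusted over the list alone. Hepatocyte transcription factors (17 members, adjusted p = 2.34e-05, and adjusted p = 0.243 with an estimated correlation) and secreted proteins (24 members, adjusted p = 1.35e-05, and adjusted p = 0.184 with an estimated correlation) moved down with 0 members passing over all genes and 0 adjusted over the list alone. The bile acid list moved down (19 members, adjusted p = 0.00198, and adjusted p = 0.140 with an estimated correlation), with 0 members passing over all genes and 1 lower adjusted over the list alone; Slc10a1, the bile acid importer, was at 104 ± 36.2 against 380 ± 67.0 CPM (adjusted p = 0.0938). Periportal genes (19 members, adjusted p = 0.000263, and adjusted p = 0.214 with an estimated correlation) moved down with 0 members passing over all genes, and 1 higher and 4 lower adjusted over the list alone. Pericentral genes (21 members, adjusted p = 0.000341, and adjusted p = 0.353 with an estimated correlation) moved down with 0 members passing by either count. The estimated correlation gave the highest adjusted p of the 14 alternatives for each of these lists, and the lowest were, in the order named, 1.89e-10, 1.6e-06, 5.02e-06, 3.76e-06, 3.69e-06, 0.000703, 0.000118 and 3.15e-05. These lists passed with any library left out. Fry lost secreted proteins (adjusted p = 0.0633), hepatocyte transcription factors (0.0735), periportal genes (0.0735) and pericentral genes (0.207). Albumin itself was at 52500 ± 43530 against 38020 ± 21180 CPM (adjusted p = 0.793).

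Markers of some other cell types moved up as lists, each with 0 members passing over all genes. T and NK cells (20 members, 0 adjusted over the list alone) had adjusted p = 0.00199, with adjusted p = 0.140 with an estimated correlation and adjusted p = 0.102 without PR-SET7_LOBE replicate 3. Macrophages and Kupffer cells (24 members, 7 higher adjusted over the list alone) had adjusted p = 0.00523, with adjusted p = 0.393 with an estimated correlation and adjusted p = 0.460 without WT replicate 2; Gpnmb was at 30.8 ± 21.8 against 0.791 ± 0.577 CPM (adjusted p = 0.0601). Stellate cells and matrix (25 members, 6 higher and 1 lower adjusted over the list alone) had adjusted p = 0.00167, with adjusted p = 0.281 with an estimated correlation and adjusted p = 0.0510 without PR-SET7_LOBE replicate 1; Col1a1 was at 21.4 ± 20.6 against 4.79 ± 3.38 CPM (adjusted p = 0.286). The interferon list (24 members, 5 higher adjusted over the list alone) had adjusted p = 0.00127, with adjusted p = 0.376 with an estimated correlation and adjusted p = 0.333 without WT replicate 2. Across the 14 alternatives the adjusted p of these lists started, in the order named, from 0.00175, 4.75e-05, 1.86e-07 and 1.02e-05, and the values with an estimated correlation were the highest except for macrophages. Erythroid markers moved down (11 members, adjusted p = 0.0107, and adjusted p = 0.243 with an estimated correlation, the highest of the 14 alternatives, with a lowest of 0.00646), with 0 passing by either count. Fry called T and NK cells (adjusted p = 0.00585) and lost macrophages (0.174), stellate cells (0.0760), the interferon list (0.145) and erythroid markers (0.138). Endothelial markers did not move as a list (20 members, adjusted p = 0.411), with 0 passing over all genes and 2 higher adjusted over the list alone. Nor did the H4K20 and chromatin methylation list (19 members, adjusted p = 0.836), with 0 passing by either count.

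**Figure D2:**
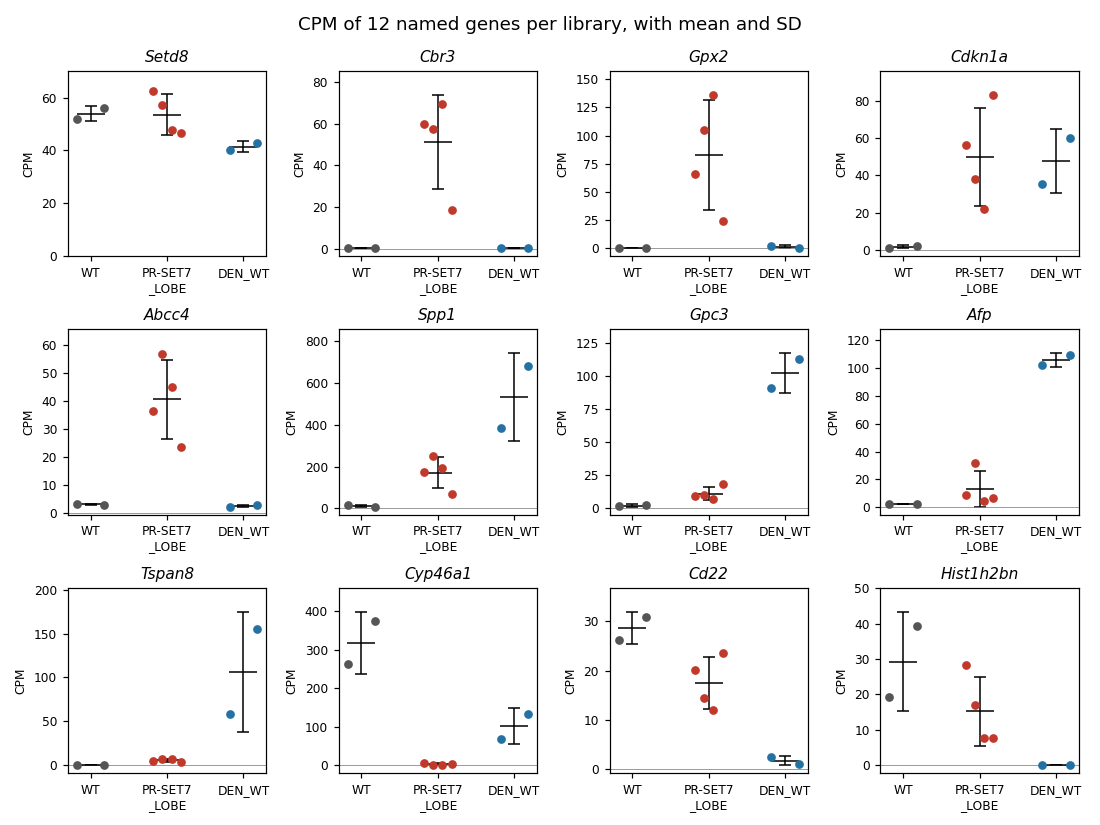
CPM of 12 named genes in each library, 1 point per library, with the mean (long bar) and SD (error bar) of WT (n = 2), PR-SET7_LOBE (n = 4) and DEN_WT (n = 2); each panel has its own linear y axis. Setd8 overlaps between WT and PR-SET7_LOBE, Cbr3 is above 18 CPM only in PR-SET7_LOBE, and Afp reaches 106 CPM on average in DEN_WT.

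The second comparison asked what DEN injection in early life leaves in the liver at 8 months. Gpc3, Afp, Tspan8 and Cdkn1a rose in DEN_WT, and Hist1h2bn, Cd3d, Cd22 and Nr1i3 fell. Gpc3, a fetal glypican (chromosome X, 49625603 to 49967127), was at 102 ± 15.3 CPM (SD, n = 2) against 1.82 ± 0.948 CPM in WT (SD, n = 2), a log2 fold change of 5.80 (SE 0.65, adjusted p = 0.00166); it overlaps other genes on both strands and is uncertain. Afp, the fetal counterpart of albumin (chromosome 5, 90919740 to 90937933), was at 106 ± 4.94 against 2.49 ± 0.000739 CPM (log2 fold change 5.40, SE 0.91, adjusted p = 0.00539). Tspan8, a tetraspanin of epithelial tumours (chromosome 10, 115254340 to 115286949), was at 106 ± 68.5 against 0.323 ± 0.456 CPM (log2 fold change 8.30, SE 1.00, adjusted p = 0.00175). Over all genes 900 rose and 789 fell, of which 443 and 637 are protein-coding and 408 and 51 are pseudogenes. The groups did not overlap in any of these 1689 genes. Here too this follows largely from the selection and is no separate support, and the 33.3% that chance gives holds for unselected genes. Akr1c18, a steroid dehydrogenase, rose by 7.95 on the log2 scale (adjusted p = 0.00209), Dnaic1 by 6.73 (adjusted p = 0.00505), Psrc1, a spindle protein, by 6.44 (adjusted p = 0.00324), Alox5, a lipoxygenase, by 6.40 (adjusted p = 0.00429) and Vil1, which bundles actin in microvilli, by 6.40 (adjusted p = 0.0312). Genes with 1 to 3 counts in WT were Cd63-ps (ratio 405, 138 to 1960), Asns, the asparagine synthetase (ratio 395, 70.6 to 15700), Gldn (ratio 275, 93.8 to 1340) and Cacna1b (ratio 189, 33.6 to 7510). Cd63-ps is 98.0% identical to Cd63 and is uncertain. No counts remained in DEN_WT for H2-M10.4 (at least 108-fold lower, adjusted p = 0.00345), Hist1h2ag (at least 61.8-fold lower, adjusted p = 0.02501) and Hist1h2ad (at least 61.5-fold lower, adjusted p = 0.0228); the last pair of genes are near-identical copies and are uncertain, as is Hist1h2bp, which has a near-identical copy. Hist1h2bp, Hist1h2bn, Hist1h2bm, H2-M10.5 and H2-M10.3 had 1 count each in DEN_WT and between 14.1 and 33.5 CPM on average in WT. How far the oligo(dT) selection shaped the histone counts was not tested. Counts at the microRNA gene entries mmu-mir-2134-2 and Mir5109 fell by 8.02 and 7.77 on the log2 scale (adjusted p = 0.00230 and 0.00321). These messenger RNA libraries do not measure mature microRNAs, so the fall is not read as a change of microRNA levels. The count of 1689 genes was 572 and 786 without WT replicates 1 and 2, 496 and 329 without DEN_WT replicates 1 and 2, and 4549 without PR-SET7_LOBE replicate 1; of 55 named genes that changed, 34, 34, 33, 32 and 55 passed in these fits, with highest adjusted p = 0.242, 0.253, 0.278 and 0.340 in the first 4. Without PR-SET7_LOBE replicates 2 and 4, 49 and 52 passed (highest adjusted p = 0.0649 and 0.0568). Afp was lost without WT replicate 1 (0.0582) and Nr1i3 without either DEN_WT library (0.0743 and 0.0616). Vil1 and Hist1h2ag were lost without WT replicate 1 (0.172 and 0.0765), WT replicate 2 (0.0931 and 0.0528), DEN_WT replicate 1 (0.0748 and 0.107) and DEN_WT replicate 2 (0.0704 and 0.127). Cacna1b was lost without WT replicates 1 and 2 and DEN_WT replicate 1 (0.117, 0.0759 and 0.0645), Hist1h2ad without WT replicate 1 and DEN_WT replicates 1 and 2 (0.0728, 0.0998 and 0.120), and Hist1h2bm without DEN_WT replicate 2 (0.0654). Voom lost Cacna1b, and the fit without a count filter lost Vil1, Hist1h2ag and Hist1h2ad (highest adjusted p = 0.0708 and 0.173 among all named genes). Without pseudogenes 1006 genes changed, 382 of them higher and 624 lower.

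With the preset correlation 6 lists moved up and 7 moved down in DEN_WT against WT. None was called with an estimated correlation (lowest adjusted p = 0.295). Fry called 6 lists, all of them up, and only 4 of these are among the 13 lists called with the preset correlation. It called 0 lists down, so none of the 7 that moved down, and it lost stellate cells and matrix (adjusted p = 0.121) and chemokines (0.149). The oncofetal list moved up with adjusted p = 3.59e-05 (adjusted p = 0.295 with an estimated correlation). Of its 23 measured members 10 rose and 13 did not pass, and 12 were higher adjusted over the list alone. The ductal and progenitor list moved up with adjusted p = 0.00679 (adjusted p = 0.295 with an estimated correlation); 7 of 24 members rose, and 9 were higher and 2 lower adjusted over the list alone. Spp1 was at 531 ± 210 against 12.3 ± 4.57 CPM (adjusted p = 0.00215) and Tnfrsf12a, a receptor for the TWEAK ligand, at 78.4 ± 6.30 against 4.66 ± 1.12 CPM (adjusted p = 0.00390), while Sox9 was at 11.6 ± 0.667 against 5.53 ± 2.87 CPM (adjusted p = 0.230). The G2 and mitosis list moved up with adjusted p = 3.59e-05 (adjusted p = 0.625 with an estimated correlation); 8 of 26 members rose and 1 fell, and 11 were higher and 1 lower adjusted over the list alone. Ccna2 rose by 3.98 (SE 0.88, adjusted p = 0.0190) and Cenpa by 2.95 (SE 0.65, adjusted p = 0.0191) on the log2 scale. Ccna2 did not pass without WT replicates 1 or 2 (0.0536 and 0.112) or DEN_WT replicates 1 or 2 (0.0907 and 0.111), nor did Cenpa without WT replicate 1 (0.116) or DEN_WT replicates 1 or 2 (0.0907 and 0.0996). Of 25 p53 targets 7 rose, and 7 were higher and 1 lower adjusted over the list alone. The p53 list as a whole did not pass (adjusted p = 0.0545, and adjusted p = 0.0363 without DEN_WT replicate 1). Cdkn1a was at 47.6 ± 17.2 CPM (log2 fold change 4.74, SE 0.72, adjusted p = 0.00327). Stellate cells and matrix moved up with adjusted p = 0.0146 (adjusted p = 0.625 with an estimated correlation, and adjusted p = 0.0991 without DEN_WT replicate 1), with Thbs1 and Lum higher among 25 members and 7 higher adjusted over the list alone. Thbs1 was lost without WT replicates 1 or 2 (0.0674 and 0.0834) or DEN_WT replicate 2 (0.133), and Lum without every WT or DEN_WT library (0.121 to 0.243), PR-SET7_LOBE replicates 2 and 4 (0.0649 and 0.0568), and with upper-quartile scaling (0.0518), GC correction (0.0682) or no pseudogenes (0.0561). Of 20 genes of the unfolded protein response 4 rose, among them Dnajb9 (101 ± 4.01 against 13.9 ± 4.41 CPM, adjusted p = 0.0235) and Xbp1 (766 ± 197 against 258 ± 27.6 CPM, adjusted p = 0.0464), and 5 were higher adjusted over the list alone. Without WT replicates 1 and 2 and DEN_WT replicates 1 and 2, neither Dnajb9 (0.162, 0.0848, 0.0736 and 0.0978) nor Xbp1 (0.242, 0.173, 0.148 and 0.333) passed. Xbp1 was also lost without PR-SET7_LOBE replicates 2 and 4 (0.0573 and 0.0550), a count filter (0.0670) or pseudogenes (0.0539). The list of the unfolded protein response moved up with adjusted p = 0.0483, which was 0.503 with an estimated correlation, 0.0646 and 0.0919 without WT replicates 1 and 2, 0.0565 and 0.0556 without PR-SET7_LOBE replicates 1 and 4, and 0.0823 without DEN_WT replicate 1. The estimated correlation gave the highest adjusted p of the 14 alternatives for all these lists. The lowest were 7.17e-07 for the oncofetal and the mitosis list, 0.000689 for the ductal and 0.000304 for the stellate list. For the p53 and the unfolded protein list the lowest (0.00505 and 0.0130) came from fry, which asks whether the list changed at all, and the lowest with camera were 0.0123 after GC correction and 0.0136 without pseudogenes. The p53 list also passed without pseudogenes (0.0143). Chemokines moved up as in PR-SET7_LOBE, with adjusted p = 0.0124 (adjusted p = 0.625 with an estimated correlation, 0.162 without WT replicate 2, and a lowest of 0.000288), and 0 of 20 members passed over all genes or adjusted over the list alone. None of 21 NRF2 and glutathione genes passed over all genes or adjusted over the list alone (list adjusted p = 0.194).

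Replication-dependent histones moved down with adjusted p = 4.08e-05 (adjusted p = 0.625 with an estimated correlation). Of 15 members 4 fell, and 9 were lower adjusted over the list alone. Mean log2 CPM of the list was 2.71 and 2.77 in WT and 0.192 and 0.227 in DEN_WT. In PR-SET7_LOBE it was 4.14, 2.36, 1.94 and 1.745. Whether the oligo(dT) selection captured histone transcripts alike in all libraries was not tested, so these levels are not read as an effect of DEN. Hepatocyte transcription factors moved down with adjusted p = 0.0125 (adjusted p = 0.625 with an estimated correlation), with 1 of 17 members lower by either count. That member was Nr1i3, the xenobiotic receptor CAR, at 29.8 ± 4.64 against 193 ± 30.4 CPM (adjusted p = 0.00358). Urea cycle genes moved down with adjusted p = 0.0266 (adjusted p = 0.625 with an estimated correlation, and adjusted p = 0.0919 without WT replicate 2), with only Ass1 lower among 22 members by either count (171 ± 35.9 against 1951 ± 2.54 CPM, adjusted p = 0.0287); Ass1 is uncertain, since it is 99.5% identical to Gm5424, and was lost without WT replicates 1 and 2 (0.0928 and 0.0892) and DEN_WT replicates 1 and 2 (0.150 and 0.213). Cytochrome P450 genes moved down with adjusted p = 0.0483 (adjusted p = 0.625 with an estimated correlation, 0.127 without WT replicate 2, 0.0777 without PR-SET7_LOBE replicate 1 and 0.0642 without pseudogenes), with 1 of 21 members lower over all genes and 4 lower adjusted over the list alone. Pericentral genes (21 members) moved down with adjusted p = 0.00679 and gluconeogenesis and glycogen (14 members) with adjusted p = 0.0310, with 0 members passing over all genes or adjusted over the list alone. With an estimated correlation each had adjusted p = 0.625, the lowest of the alternatives were 0.00254 and 0.00811, and gluconeogenesis was lost without WT replicate 2 (0.143). Fatty acid oxidation (17 members, 1 lower by either count) had adjusted p = 0.0483, which was 0.673 with an estimated correlation, 0.549 without WT replicate 2, 0.0585, 0.0529, 0.0524 and 0.0634 without PR-SET7_LOBE replicates 1 to 4, 0.0823 without DEN_WT replicate 1, 0.0513 with RLE scaling, 0.0692 without pseudogenes, and at its lowest 0.000895. Of 20 genes of lipogenesis and lipid droplets 4 fell and 1 rose, and 7 were lower and 1 higher adjusted over the list alone, with the list at adjusted p = 0.0545. That list passed without WT replicate 1 (adjusted p = 0.00262), PR-SET7_LOBE replicate 3 (0.0451) or DEN_WT replicate 2 (0.0310). Acacb, an acetyl-CoA carboxylase, was at 77.9 ± 31.9 against 634 ± 136 CPM (adjusted p = 0.00683), and was lost without DEN_WT replicates 1 and 2 (0.101 and 0.0535). The lowest adjusted p of the 14 alternatives was 9.72e-08 for histones, 0.00482 for transcription factors, 0.00869 for the urea cycle, 0.00549 for cytochrome P450 and 0.00262 for lipogenesis, and the highest, with an estimated correlation, was 0.625 for each. Lymphocyte lists did not move as a whole (adjusted p = 0.427 for each), but 3 of 20 T and NK cell genes and 2 of 14 B and plasma cell genes fell, with the same counts adjusted over the list alone; Xbp1, a B and plasma cell list member shared with the unfolded protein response, rose. Cd3d, a T cell receptor subunit, was at 0.310 ± 0.0631 against 13.8 ± 0.297 CPM (adjusted p = 0.00237), Cd22, a B cell lectin, at 1.64 ± 0.941 against 28.6 ± 3.29 CPM (adjusted p = 0.00231) and Fcer2a at 0.266 ± 0.251 against 12.6 ± 2.26 CPM (adjusted p = 0.00258).

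**Figure D3:**
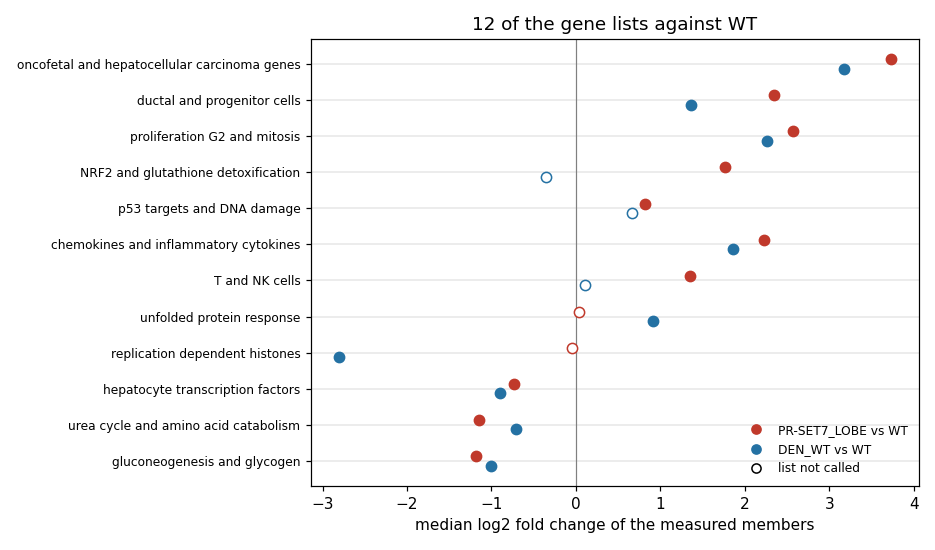
Median log2 fold change against WT (x axis) of the measured members of 12 gene lists (y axis) in PR-SET7_LOBE and DEN_WT, with members that had 0 counts in all libraries of a group set to their bound; filled points mark lists called with the preset correlation. The oncofetal list has the highest medians (3.73 and 3.18), and the NRF2 list is called only in PR-SET7_LOBE.

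The third comparison set PR-SET7_LOBE against DEN_WT directly and tests the difference between their effects. Cbr3, Abcc4, Hist1h2bn and Cd3d were higher in the libraries labelled PR-SET7_LOBE, and Gpc3, Afp and Tspan8 were lower. Cbr3 was at 51.5 ± 22.6 CPM (SD, n = 4) against 0.442 ± 0.000796 CPM in DEN_WT (SD, n = 2), a log2 fold change of 6.83 (SE 0.73, adjusted p = 0.000746). Gpc3 was lower (log2 fold change -3.21, SE 0.44, adjusted p = 0.00143), as were Afp (-3.01, SE 0.62, adjusted p = 0.0105) and Tspan8 (-4.27, SE 0.59, adjusted p = 0.00157). The oncofetal list did not move as a whole (adjusted p = 0.797, median log2 fold change 0.46), with 1 of 23 members higher, 3 lower and 19 not passing. Of 17362 genes 837 were higher and 1087 lower, and pseudogenes made up 41 and 669 of these. The groups did not overlap in 1919 of the 1924 genes. Again this follows largely from the selection and is no separate support, and the 13.3% that chance gives holds for unselected genes. Hist1h2ad and Hist1h2ag had no counts in DEN_WT and were at least 58.8-fold and 58.3-fold higher in PR-SET7_LOBE (adjusted p = 0.0165 and 0.0186), and H2-M10.4 was at least 24.9-fold higher (adjusted p = 0.00668). Hist1h2ad, Hist1h2ag and Hist1h2bp have near-identical copies and are uncertain here too. Hist1h2bp and Hist1h2bn had 1 count each in DEN_WT, with ratios of 364 (65.1 to 14400) and 343 (61.4 to 13600). Counts at the entry mmu-mir-2134-2, which are no level of a mature microRNA, were higher by 7.63 on the log2 scale (adjusted p = 0.00151). Cyp46a1 was at 2.96 ± 2.82 against 101 ± 46.5 CPM (adjusted p = 0.00142) and H2-Ea-ps at 0.115 ± 0.137 against 14.2 ± 3.79 CPM (adjusted p = 0.000934), so both were lower in PR-SET7_LOBE than in either other group. For Cyp46a1 and H2-Ea-ps a strain difference is not separated from the group, as above. Akr1c18 was lower by 5.27 (adjusted p = 0.00107), Eif5al3-ps by 6.05 (adjusted p = 0.000746), Cd63-ps by 5.04 (adjusted p = 0.00157) and Psme2b-ps by 5.01 (adjusted p = 0.00381) on the log2 scale; the 3 pseudogenes have near-identical parent genes and are uncertain. Cdkn1a did not differ beyond its error (log2 fold change 0.06, SE 0.52, adjusted p = 0.949). The count of 1924 genes was 714 and 454 without DEN_WT replicates 1 and 2, where 21 and 16 of 30 named genes that changed passed (highest adjusted p = 0.342 and 0.261), and 957 without pseudogenes, of which 613 were higher and 344 lower. Without PR-SET7_LOBE replicates 2 and 3, 28 and 29 named genes passed (highest adjusted p = 0.0759 and 0.0503). Afp (0.0598) and H2-M10.4 (0.0611) were lost without DEN_WT replicate 2. Hist1h2ad and Hist1h2ag were lost without DEN_WT replicate 1 (0.0873 and 0.0949), without replicate 2 (0.108 and 0.118) and without a count filter (0.0504 and 0.0789).

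With the preset correlation 6 lists were higher and 3 lower in PR-SET7_LOBE than in DEN_WT, none with an estimated correlation (lowest adjusted p = 0.171), and fry called 4. The NRF2 and glutathione list was higher with adjusted p = 1.86e-08 (adjusted p = 0.625 with an estimated correlation); 10 of 21 members were higher over all genes, and 15 adjusted over the list alone. Besides Cbr3 they include Abcc4 (log2 fold change 3.98, SE 0.49, adjusted p = 0.00111), Gsta1 (5.82, SE 0.76, adjusted p = 0.00132, uncertain as above) and Cbr1 (192 ± 80.7 against 17.8 ± 1.66 CPM, adjusted p = 0.00328). Histones were higher with adjusted p = 3.21e-05 (adjusted p = 0.914 with an estimated correlation), in 8 of 15 members over all genes and 12 adjusted over the list alone. The limit on the capture of histone transcripts given above holds here too. T and NK cell genes were higher with adjusted p = 0.000305 (adjusted p = 0.171 with an estimated correlation), in 3 of 20 members over all genes and 3 adjusted over the list alone; Cd3d was at 7.64 ± 4.25 against 0.310 ± 0.0631 CPM (adjusted p = 0.00244). B and plasma cell genes were higher with adjusted p = 0.0111 (adjusted p = 0.725 with an estimated correlation), with 3 of 14 members higher and 1 lower over all genes, and 5 higher and 1 lower adjusted over the list alone. Neutrophil genes were higher with adjusted p = 0.0119 (adjusted p = 0.737 with an estimated correlation), in 2 of 10 members over all genes and 3 adjusted over the list alone; Csf3r was at 19.7 ± 5.69 against 2.79 ± 1.07 CPM (adjusted p = 0.00306). The unfolded protein response was lower with adjusted p = 0.00123 (adjusted p = 0.171 with an estimated correlation), in 3 of 20 members by either count. These were Xbp1 (240 ± 23.7 against 766 ± 197 CPM, adjusted p = 0.0120), Dnajb9 (18.8 ± 9.80 against 101 ± 4.01 CPM, adjusted p = 0.0118) and Asns (2.38 ± 1.83 against 18.6 ± 5.09 CPM, adjusted p = 0.0155). None of these 3 passed without DEN_WT replicates 1 or 2: Xbp1 had adjusted p = 0.0578 and 0.245, Dnajb9 0.0518 and 0.0773, and Asns 0.0502 and 0.160. Cbr1 was lost in the same fits (0.0553 and 0.0592), and Csf3r (0.0852) and Cd3d (0.0519) without DEN_WT replicate 2. Male-biased liver genes were lower with adjusted p = 0.0216 (adjusted p = 0.988 with an estimated correlation, 0.134, 0.212 and 0.115 without PR-SET7_LOBE replicates 2 and 3 and DEN_WT replicate 1, and 0.0693 after GC correction), in 3 of 24 members over all genes and 4 adjusted over the list alone. The estimated correlation gave the highest adjusted p of the 14 alternatives for each list, and the lowest were, in the order named, 1.49e-09, 3.44e-07, 0.000163, 0.00211, 0.000673, 2.39e-05 and 0.00197.

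Across the 17362 genes the log2 fold changes of PR-SET7_LOBE and DEN_WT against WT correlated at r = 0.502, where simulated unchanged groups against the same WT libraries gave 0.541 (0.518 to 0.563 in 20 simulations). Genes are not independent replicates, and shared controls alone give such a correlation. The covariance was 1.62 against 0.387 in the simulations (0.367 to 0.400), a difference of 1.23. The covariance was 2.66 and 3.41 without WT replicates 1 and 2, and r was 0.595 and 0.659. It thus rose when a single WT library served as control, so the simulations may understate the variation of the WT libraries. Among genes with a mean log2 CPM of 3 or more it was 0.584, for which no simulation was run. The difference of 1.23 is therefore not read as a shared effect. Of the genes that rose, 13 rose in both comparisons, where independent lists would share 1.35. The simulations gave 0, but they hold no effects and so hardly any calls, and this 0 says nothing on overlap from shared controls. They were Cdkn1a, Phlda3, Spp1, Igdcc4, Fabp4, Gldn, Phlda2, Ppfia4, Cxcr4, Itgax, Tubb2b, 5330417C22Rik and 6030419C18Rik, of which the last 5 were named after their values were seen. Only Gm4477, also named after its values were seen, fell in both (0.773 for independent lists), and 0 genes rose in one and fell in the other. The controls were not split, because each part would hold a single WT library, so part of the overlap may come from the shared controls.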

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

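Of the tests below, the count of genes far above the WT libraries, the contrast of processed with unprocessed pseudogenes, the reading of DEN treatment, the GC correction and the fit without pseudogenes were chosen only after the result was seen.

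PR-SET7_LOBE replicate 1 correlated more with WT (mean r = 0.923) than with the other PR-SET7_LOBE libraries (mean r = 0.890), and without it 2392 genes changed against WT in place of 43. A GC trend may explain part of this: the difference of the mean r went from -0.0335 to -0.0123 (-0.0157 to -0.00989) after GC correction, which leaves the rest unexplained. A mislabelled WT liver is argued against by 75 genes at least 16-fold above both WT libraries at 5 CPM or more, where the WT libraries gave 15 and 25 against each other and PR-SET7_LOBE replicates 2 to 4 gave 88, 93 and 82. Of the 1271 genes higher without this library, it lay above both WT libraries in 51.3% (48.5 to 54.1), a share that choosing genes low in WT raises, so this decides little alone. A smaller share of affected cells could also give this pattern and was not tested.

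Pseudogenes were higher in the DEN_WT libraries than in WT, with a median log2 fold change of 2.89 against -0.02 for protein-coding genes. The GC trend is argued against, since the difference of the medians was 2.89 (2.64 to 3.06) after correction and 2.91 before. Near-identical pseudogenes exceeded the others by 0.295 (-0.379 to 1.42), which cannot decide whether reads shared with a parent gene were counted by another rule. Processed pseudogenes exceeded unprocessed ones by 3.22 (2.51 to 3.89), which may reflect reads of spliced transcripts placed on them by another alignment or counting rule, but at 95% identity or more the medians were 2.94 (801 processed) and 1.60 (25 unprocessed), and pseudogenes with a match of 85% or more had 3.02 against -0.32 without, so processing and likeness to a parent gene are not separated. DEN treatment could not be separated from such a rule, because 0 treated libraries lie outside the group, so the 408 pseudogenes that rose are not read as an effect of DEN.

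NRF2 and glutathione genes were higher in PR-SET7_LOBE than in DEN_WT, with a mean log2 fold change of 2.50 over the list (adjusted p = 1.86e-08, and adjusted p = 0.625 with an estimated correlation), and the list tests below use the preset correlation. A GC trend is argued against by a mean of 2.52 after correction. Reads shared between paralogs are argued against by a mean of 2.32 over the 18 members without a close copy (adjusted p = 7.15e-07). No single PR-SET7_LOBE library carries it, since the highest adjusted p with any of them left out was 1.49e-07. A processing difference of the DEN_WT libraries remains confounded with DEN treatment, so the difference is not called biological here; the same list was also higher against WT (adjusted p = 4.12e-09, and adjusted p = 0.184 with an estimated correlation).

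Single PR-SET7_LOBE libraries lay apart from the other 3 of their group in 5 of 133 values (3.76%), where chance gives about 5%. Phlda2 had 17.4 CPM in replicate 3 (4.46 to 6.01 in the others), Afp 32.1 CPM in replicate 2 (4.83 to 8.92), Vil1 59.5 CPM in replicate 1 (3.55 to 9.76), Thrsp 178 CPM in replicate 3 (640 to 696) and Cbr1 72 CPM in replicate 4 (221 to 242). Between PR-SET7_LOBE and DEN_WT 1924 genes differed. So did 9 lists: NRF2 and glutathione (adjusted p = 1.86e-08), T and NK cells (0.000305), histones (3.21e-05), B and plasma cells (0.0111), neutrophils (0.0119) and S phase (0.0374) were higher in PR-SET7_LOBE, and the unfolded protein response (0.00123), male-biased genes (0.0216) and secreted proteins (0.0323) were lower. None passed with an estimated correlation: in the order named, adjusted p = 0.625, 0.171, 0.914, 0.725, 0.737, 0.939, 0.171, 0.988 and 0.939, the highest of the 14 alternatives for each. S phase was also lost without WT replicates 1 and 2 (0.0522 and 0.0568), PR-SET7_LOBE replicates 2 and 3 (0.0737 and 0.147) and DEN_WT replicate 2 (0.0937). Secreted proteins were lost without PR-SET7_LOBE replicates 3 and 4 (0.389 and 0.0743), and male-biased genes without PR-SET7_LOBE replicates 2 and 3 (0.134 and 0.212), without DEN_WT replicate 1 (0.115) and after GC correction (0.0693). The fit without pseudogenes also lost S phase (adjusted p = 0.0528). The lowest adjusted p of the 14 alternatives was 0.0111 for S phase, 0.00269 for secreted proteins and 0.00197 for male-biased genes.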

How the results depend on the processing

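No named gene and no list changed direction and passed in the alternatives compared for it. Directions of named genes were not compared with voom or the fit on only 2 groups, except for Setd8. Lists were tested with RLE scaling, the block, each library left out, GC correction, without pseudogenes, an estimated correlation and fry, and not in the other fits. For PR-SET7_LOBE against WT the 43 genes became 66 with upper-quartile scaling, 927 with DESeq2, 386 with voom, 419 without a count filter, 19 with only the 2 groups, and 138 after GC correction. Leaving out 1 library gave 1 (WT replicate 2) to 2392 genes (PR-SET7_LOBE replicate 1). DESeq2 made 30 false calls in the simulated data of this comparison (16107 genes), so its count is read with care. Voom put 133 genes higher and 253 lower, where edgeR put 26 and 17. Setd8 stayed between -0.11 and 0.16 on the log2 scale and was called by no alternative.

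For DEN_WT against WT the 1689 genes became 3144 with DESeq2, 6335 with voom, 5643 with only the 2 groups and 1006 without pseudogenes, and ran from 329 (without DEN_WT replicate 2) to 4549 (without PR-SET7_LOBE replicate 1). For PR-SET7_LOBE against DEN_WT the 1924 genes became 5188 with voom and 957 without pseudogenes, and ran from 454 (without DEN_WT replicate 2) to 2662 (without PR-SET7_LOBE replicate 1).

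The list tests called 30, 13 and 9 lists in the 3 comparisons. With an estimated correlation they called 0, 0 and 0, and fry called 10, 6 and 4. Of the lists called by fry, 10, 4 and 4 were also called with the preset correlation. Leaving out 1 library gave 7 (WT replicate 2) to 16 lists (DEN_WT replicate 2) for DEN_WT against WT.

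With the replicate number as a block, 243 genes changed in PR-SET7_LOBE against WT and 3137 in DEN_WT against WT, and 5 lists passed between PR-SET7_LOBE and DEN_WT. The 4 lists lost there were B and plasma cells (adjusted p = 0.140), neutrophils (0.153), S phase (0.140) and secreted proteins (0.683). In DEN_WT against WT the unfolded protein response (0.0624) and fatty acid oxidation (0.0635) were lost, and in PR-SET7_LOBE against WT homologous recombination (0.447), neutrophils (0.141) and the circadian clock (0.141). The labels do not say what a shared replicate number means. Deviations of libraries with the same number correlated at 0.0599 for WT with DEN_WT, 0.165 and 0.106 for WT with PR-SET7_LOBE, and -0.00874 and 0.0200 for PR-SET7_LOBE with DEN_WT. In a group of 2 libraries the deviations mirror each other, so each value comes with its opposite, such as -0.165 for WT replicate 2 with PR-SET7_LOBE replicate 1. WT replicate 2 with PR-SET7_LOBE replicate 4 gave 0.16. The check can therefore hardly show or exclude pairing. The libraries were treated as unpaired because the labels state no pairing. The correlation of both effects against WT was 0.403 in the fit with the block.

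That correlation was 0.582 among genes with a mean log2 CPM of 3 or more, 0.618 without pseudogenes, and 0.449 (without PR-SET7_LOBE replicate 3) to 0.659 (without WT replicate 2). Its covariance was 0.584 among genes with a mean log2 CPM of 3 or more and ran from 1.13 to 3.41 over the same libraries. RLE scaling, the strict filter and leaving out the 20 most abundant genes changed no named call among the 137, 130 and 135 results they measured. The strict filter did not measure 2 of the 55 named genes that changed in DEN_WT against WT. An alternative for normalised values was not run, because the files hold counts.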

Other observations

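The genes in this part were chosen after their values were seen and are given as values without a test here. H19 and Igf2 also belong to the oncofetal list, and Sult2a1 and Cyp4a12a to the female-biased and male-biased lists, which were tested above. H19 and Igf2, imprinted neighbours active in fetal liver, were high in only some PR-SET7_LOBE libraries. H19 had 6959, 9387, 9.66 and 109 CPM in replicates 1 to 4, against 0.383 and 0.369 CPM in WT and 576 and 138 CPM in DEN_WT. Igf2 had 2419, 2030, 1.76 and 5.65 CPM in the same replicates, against 1.15 and 1.48 CPM in WT and 10.6 and 3.80 CPM in DEN_WT; it shares sequence with Gm49394 and is uncertain.

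Gpx2, a named gene, had 66.1, 105, 136 and 23.9 CPM in the PR-SET7_LOBE libraries, 0 counts in WT, and 1.95 and 0.0883 CPM in DEN_WT. Sult2a1, which is female-biased in mouse liver and uncertain because Sult2a2 is 98.5% identical to it, had 209 CPM in PR-SET7_LOBE replicate 2 and at most 5.83 CPM in the other 7 libraries. Cyp4a12a, which is male-biased and uncertain because it is 98.3% identical to Cyp4a12b, had 22.3 CPM in that library and between 89.5 and 713 CPM in the others. Mean log2 CPM of the male-biased list was 4.075 in that library and between 5.03 and 7.54 in the others. For the female-biased list it was 4.82 in that library and between 2.11 and 3.98 in the others.

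Mup-ps22 had 2382 and 3311 CPM in DEN_WT and at most 4.79 CPM in the other 6 libraries. The Y-linked Ddx3y had 5.65 and 4.43 CPM in WT, 2.72, 2.97, 12.6 and 14.6 CPM in PR-SET7_LOBE, and 45.1 and 32.3 CPM in DEN_WT. Kdm5d, also Y-linked, had 7.37 and 5.72, then 1.88, 2.01, 7.055 and 13.3, then 12.2 and 12.1 CPM in the same order. In DEN_WT Eif2s3y had 40.3 and 28.4 CPM and Uty 9.74 and 8.83 CPM, above all other libraries. Eif2s3y was lowest in PR-SET7_LOBE replicates 1 and 2, at 2.54 and 1.72 CPM, where WT had 8.135 and 8.94 CPM. Every library held counts of each of these Y-linked genes, but the sex of the samples was not tested.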
